A study of Mus musculus with 30 samples.

How the data were processed

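RNA of pooled mouse embryonic ovaries was measured at 5 ages, 11.5, 12.5, 14.5, 16.5 and 18.5 days post coitum (dpc), with 2 numbered RNA samples per age. Each of the 10 sample numbers has arrays of 3 Affymetrix types, called A, B and C here, which carry different probe sets, giving 30 arrays. Per the labels, the mice were of a mixed C57BL/6 and 129 background, total RNA was extracted with TRIzol, and the gonads of the youngest ages were sexed by PCR for the male gene Sry. The labels do not say that the 2 samples of an age came from separate pools of ovaries, so every p-value measures the spread between these samples, which may be technical. They also do not state that the A, B and C arrays of one number received the same RNA. Each array type was fitted on its own, but the arrays of one number were treated as 1 sample where a sample was left out and where control ratios were averaged. They were also treated so where the correlation between the genes of a list was estimated and in the fry test, both described below. The results of these 2 steps rest on that assumption.

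The deposited values were signal intensities, 1 per probe set and array, which the authors had scaled to a mean signal of 125, per the labels. The mean after trimming 2% of the values at each end lay between 125.02 and 125.08 on the 30 arrays. The software that made the signals is not given in the sources used here, and no detection calls were used, so a low signal was never called absent. The arrays held 36899 probe sets, of which 198 were controls. In the platform annotation 29131 probe sets had 1 gene symbol, 724 had several and 6846 had none, and only probe sets with 1 symbol were given a gene name. The symbols were compared with a RefSeq gene table (assembly GRCm38.p6, used for names only). No symbol changed, and 87 Entrez identifiers were not in that table.

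Signals were analysed as log2(signal + 16). A fold change below is a fold on that scale, which understates the change of genes with low signal. A probe set was tested when its signal reached 50 on at least 2 of the 10 arrays of its type. This kept 24825 of 36701 probe sets (7494 on array A, 9103 on B and 8228 on C), standing for 12589 named genes. One linear model with the 5 ages as groups was fitted per array type with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), so all 10 arrays of a type shared 1 estimate of the spread, with 5 residual degrees of freedom per probe set. The comparisons were each age against the age before it, 18.5 against 11.5 dpc, and an F test over the 5 ages. P-values were adjusted by the Benjamini-Hochberg method over the 3 array types together, and an adjusted p under 0.05 was called. Errors of signals are SDs over 2 samples and errors of log2 changes are standard errors of the model. The number of arrays limits the precision.

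A gene was represented by its tested probe set with the highest mean log2 signal, across the array types. Each type was scaled to the same mean, so signals of different types are not on a common scale. The 3 prime Gapdh signal of 11.5 dpc replicate 1, for example, was 5361.9 on array A, 11110.7 on B and 27947.5 on C. The choice can therefore favour a probe set on array B or C over 1 on array A. For some named genes the chosen probe set had an added f, i or r in its suffix in place of the plain _at. Among them were Terb1, Meioc, Cspp1, Il33, Trmt13, Sox2, Sox9, Naaa, Hbb-y, H2-K2, Nlrp4f, Stag3, Skp2, Cpne8, Apoa1, Wnt4, Zp2, Sycp3 and Trim71. Such probe sets may not be specific to the gene, which was not checked gene by gene. Named genes followed a rule set before the data were examined. For each interval the 6 largest rises and the 6 largest falls were named, and for 18.5 against 11.5 dpc the 10 largest of each. They had to be called, with both samples of one age on the same side of both samples of the other, and with a mean signal of at least 100 at the higher age. Up to 4 called members per gene list were also eligible, as was a fixed set of well-known genes of germ cells, oocytes and supporting cells. Also fixed beforehand were 24 gene lists. Of their entries 820 matched a symbol of the gene table as written, 2 matched through a synonym and 2 did not match. Lists were tested with limma's cameraPR on the moderated t values of the genes with a preset inter-gene correlation of 0.01, adjusted over 115 tests (23 lists with at least 5 tested members in 5 comparisons). The same test was repeated with a correlation estimated from the residuals of the fit. A rotation test of each list by itself, limma's fry, was also run and adjusted over the 115 tests. Its result is given where a list passed both camera tests but not fry. Beside the calls over all probe sets, members were counted with p-values adjusted over the list alone.

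The procedure was tested on simulated data with the means and residual spreads of the real probe sets, 24825 in all, and changes placed at 18.5 dpc. In 18.5 against 16.5 dpc the fit called 90 of 300 probe sets changed 2-fold, 215 of 300 changed 4-fold and 14 of 24225 unchanged ones. Of 500 random lists of 30 genes, 1.6% had a p under 0.05 in the list test. The simulated probe sets varied independently of each other, so this share does not hold for genes that vary together. In the real data the estimated correlation of a list reached 0.27, for the ribosomal protein genes.

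The alternatives tried were pseudocounts of 1 and 32, no filter, a filter at a signal of 100, quantile normalization, scaling to a common median, no intensity trend, adjustment within each array type, the replicate number as a block, each sample left out in turn, only the 2 ages compared, and an added 2-fold limit. For the lists they were also the estimated correlation, the mean t of all probe sets of a gene, array A alone and, added after the data were seen, only probe sets with the plain suffix. Figures were drawn with matplotlib 3.10.9. Control probe sets were left out of all tests.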

Results

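Transcript levels were followed in the mouse ovary from 11.5 dpc, when the gonad is newly formed, to 18.5 dpc, shortly before birth. Each age was represented by 2 numbered samples of pooled ovaries, with an array A, B and C for each number. Between 48.8% and 63.0% of the probe sets of an array had a signal of at least 50, and the median signal ranged from 47.0 to 81.7. Pearson's r between the 2 samples of an age, across tested probe sets on the log2 scale, was 0.950 to 0.974 on array A, 0.877 to 0.920 on array B and 0.856 to 0.896 on array C. Between samples of 11.5 and 18.5 dpc it was 0.856 to 0.862 on array A. Samples of neighbouring ages were in places as close as replicates: the 2 samples of 11.5 dpc had an r of 0.950 on array A and 0.877 on array B, against up to 0.960 and 0.880 with samples of 12.5 dpc, and those of 16.5 dpc had 0.856 on array C, against up to 0.859 with a neighbouring age. These correlations run across genes, which are not independent replicates. Among the control probe sets, the ratio of the 3 prime to the 5 prime Gapdh signal, averaged over the 3 arrays of a number, lay between 0.829 and 0.845 in the 4 samples of 11.5 and 12.5 dpc. In replicates 1 and 2 it was 0.885 and 0.951 at 14.5 dpc, 0.917 and 1.09 at 16.5 dpc, and 1.08 and 1.05 at 18.5 dpc. The b-actin ratio ranged from 1.18 in 12.5 dpc replicate 1 to 2.19 in 14.5 dpc replicate 2. The ratio of the TransRec control ranged from 2.28 in 11.5 dpc replicate 1 to 3.60 in 14.5 dpc replicate 2. That of the PyruCarb control ranged from 0.966 in 11.5 dpc replicate 2 to 3.07 in 14.5 dpc replicate 1. These ratios did not move steadily with age, but the Gapdh ratio was higher at the later ages. A difference in RNA quality that goes with age could therefore not be excluded.

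Germ cell genes followed a sequence over the 5 ages. The pluripotency factor Pou5f1 had its highest mean signal at 12.5 dpc (417 ± 147, SD, n = 2), Stra8, which is needed for entry into meiosis, at 14.5 dpc (598 ± 143), and the oocyte transcription factors Lhx8 (634 ± 63.9) and Nobox (599 ± 2.9) at 18.5 dpc. Sycp1, a protein of the synaptonemal complex, had mean signals of 2.2, 10.2, 322, 679 and 903 in order of age. Foxl2, a transcription factor of supporting cells of the ovary, had 92.0, 168, 351, 825 and 730. In the F test over the 5 ages 3565 of 24825 probe sets (14.4%) passed the threshold. Of these, 1038 (29.1%) had their highest mean at 18.5 dpc, 843 at 11.5 dpc, 657 at 16.5 dpc, 625 at 12.5 dpc and 402 at 14.5 dpc. The share of tested probe sets that passed was 21.7% on array A, 13.5% on array B and 8.68% on array C. Without 18.5 dpc replicate 1 the count was 1812, without 18.5 dpc replicate 2 it was 1957, and without 12.5 dpc replicate 1 it was 2346.

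**Figure D1:**
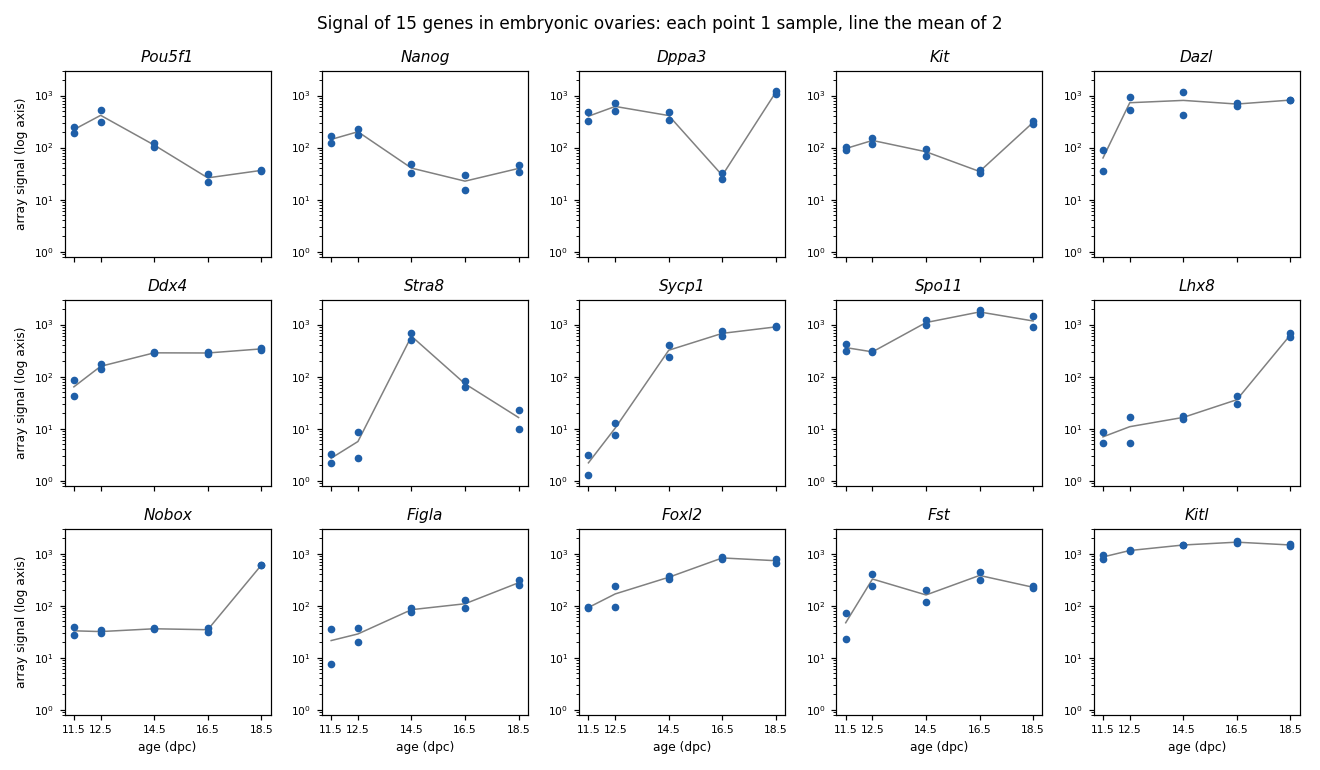
Array signal (log axis, scaled units) of 15 genes against age in dpc, with 1 point per sample and a line through the mean of the 2 samples of each age. Stra8 peaks at 14.5 dpc at a mean of 598, and Lhx8 and Nobox reach 634 and 599 at 18.5 dpc. Signals of genes read on different array types are not on a common scale.

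From 11.5 to 12.5 dpc the largest rises among the named genes were in Dazl, Ap2b1 and Fst. Dazl, an RNA-binding protein of germ cells, rose 9.70-fold, from a signal of 63.2 ± 40.0 to 729 ± 279 (SD, n = 2; limma adjusted p = 0.012). The other Dazl probe set changed less, from 42.1 and 43.6 in the samples of 11.5 dpc to 92.7 and 63.0 in those of 12.5 dpc. Ap2b1, a subunit of the clathrin adaptor complex, rose 6.20-fold to 556 ± 75.0. Fst, the activin antagonist follistatin, rose 5.67-fold to 325 ± 125, and the homeobox gene Irx3 rose 4.51-fold to 273 ± 82.9. The other Fst probe set changed less, from 78.9 and 131.7 in the samples of 11.5 dpc to 191.8 and 128.8 in those of 12.5 dpc. Lgals7, a galectin, and Acsbg1, an acyl-CoA synthetase, rose 3.82-fold and 3.73-fold. Among the falls, the lysosomal amidase Naaa fell from 1719 to 618 (2.69-fold), and lipoprotein lipase, Lpl, from 308 to 106 (2.67-fold). Pls3, an actin-bundling protein, Actr6, Cebpd and Rnf19a fell by 2.20-fold, 2.09-fold, 1.99-fold and 1.78-fold.

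As groups, the germ cell lists were higher at 12.5 dpc in the camera test. Of 23 tested genes of primordial germ cells and pluripotency none passed over all probe sets, and 9 rose when adjusted over the list alone. Their median log2 change was 0.57 (limma camera adjusted p = 1.1e-08, and adjusted p = 0.0047 with an estimated correlation). Of 16 genes of germ cell RNA and piRNA machinery Dazl rose over all probe sets and 4 did when adjusted over the list alone (median log2 change 0.35, adjusted p = 2.1e-05, and adjusted p = 0.0047 with an estimated correlation). With fry the germ cell RNA and piRNA list did not pass (adjusted p = 0.074). Among the members that did not pass, Ddx4 had signals of 63.6 ± 31.0 and 158 ± 28.6, and Pou5f1 had 222 ± 40.4 and 417 ± 147. Of 32 genes of pregranulosa and supporting cells Fst and Irx3 rose and 30 did not pass, and 4 rose and 1 fell when adjusted over the list alone (adjusted p = 0.0010, but adjusted p = 0.33 with an estimated correlation, and 0.097 and 0.29 without 11.5 dpc replicate 1 and 12.5 dpc replicate 1). Of 39 mesenchyme and matrix genes none passed over all probe sets and 5 rose when adjusted over the list alone (list adjusted p = 0.0058, but adjusted p = 0.42 with an estimated correlation, and 0.051 and 0.18 without 11.5 dpc replicate 1 and 12.5 dpc replicate 2). Of 18 erythroid genes Hbb-b2, an adult globin, rose 2.60-fold, and 2 rose when adjusted over the list alone (list adjusted p = 0.0092, but adjusted p = 0.17 with an estimated correlation, and 0.056 and 0.18 without replicate 2 of 11.5 and of 12.5 dpc).

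In all, 56 probe sets changed, 49 of them upward and 7 downward (a more even split without 11.5 dpc replicate 2), and 3090 had an unadjusted p under 0.05. This count was the least stable of the 5. It was 2 without 12.5 dpc replicate 2, 4 without 12.5 dpc replicate 1, 13 without 11.5 dpc replicate 1 and 553 without 11.5 dpc replicate 2, and without either sample of 12.5 dpc neither Dazl (adjusted p = 0.23 and 0.088 without replicates 1 and 2), Fst (0.25 and 0.10) nor Ap2b1 (0.11 and 0.088) passed.

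From 12.5 to 14.5 dpc the largest rises were in genes of meiosis. Terb1, which tethers telomeres in meiosis, rose 34.4-fold, from 4.0 ± 1.5 to 674 ± 59.7 (SD, n = 2; limma adjusted p = 9.7e-06). Meioc, a meiosis-specific coiled-coil protein, rose 33.5-fold, from 1.2 to 587, and Stra8 28.2-fold, from 5.7 ± 4.2 to 598 ± 143. Sycp1 rose 12.5-fold and Tex12, another synaptonemal complex protein, rose 10.5-fold from 277 ± 4.2 to 3077 ± 237. Ugt8a, a galactosyltransferase, rose 10.2-fold. Of 29 tested genes of meiotic prophase 12 rose, none fell and 17 did not pass, and 15 rose when adjusted over the list alone. Their median log2 change was 1.14 (camera adjusted p = 1.3e-40, and adjusted p = 8.1e-22 with an estimated correlation). Spo11, which makes the meiotic double-strand breaks, went from 299 ± 9.0 to 1096 ± 180 (adjusted p = 0.0034), the cohesin Rec8 from 656 ± 32.8 to 1565 ± 3.1 (adjusted p = 0.026) and the recombinase Dmc1 from 28.1 ± 6.9 to 103 ± 36.3 (adjusted p = 0.020). Sycp3 was not called, with 7.7 ± 2.1 and 138 ± 60.2 (adjusted p = 0.070). In the germ cell RNA and piRNA list 4 of 16 genes rose, and 9 did when adjusted over the list alone (adjusted p = 5e-09, and adjusted p = 7.1e-05 with an estimated correlation), but on array A alone the list was not called (adjusted p = 0.37). Tex101 rose 4.74-fold, Gtsf1 4.32-fold and Mov10l1 2.30-fold.

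Part of the pluripotency genes fell over the same interval. Of 23 genes of primordial germ cells and pluripotency 10 fell, none rose and 13 did not pass, and 15 fell and 1 rose when adjusted over the list alone. The median log2 change was -1.02 (camera adjusted p = 1.1e-16, and adjusted p = 1.8e-05 with an estimated correlation). Esrrb, a nuclear receptor of the pluripotency network, fell 5.98-fold, Zfp42 3.98-fold, Nanog 3.86-fold (202 ± 43.1 to 40.4 ± 10.3) and Utf1 3.41-fold. Pou5f1 fell to 112 ± 13.6 (adjusted p = 0.0031). Other large falls were in Cpa1, a carboxypeptidase (9.68-fold), Sprr2d (8.18-fold), Ap2b1 (6.55-fold, back to 75.8 ± 41.1), the embryonic globin Hba-x (5.60-fold, 4514 ± 619 to 790 ± 69.2) and the DNA repair gene Alkbh2 (5.49-fold).

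Of 15 genes of surface and mesothelial epithelium 5 rose, and 7 rose and 1 fell when adjusted over the list alone. The rises included the keratins Krt19 (3.70-fold), Krt18 (2.40-fold) and Krt8 (2.27-fold) and the uroplakin Upk3b (2.31-fold; list adjusted p = 2.1e-05, and adjusted p = 0.048 with an estimated correlation). Of 20 endothelial genes Emcn fell, 2.15-fold, and 5 fell when adjusted over the list alone (list adjusted p = 0.0013, and adjusted p = 0.0047 with an estimated correlation). Of 51 genes of cell cycle and DNA replication Rrm2, Mcm7 and Mcm2 fell, the first by 1.75-fold and the next by 1.72-fold, and 8 fell and 2 rose when adjusted over the list alone (list adjusted p = 3.6e-05, but adjusted p = 0.053 with an estimated correlation). None of 31 ribosomal protein genes passed, and the call of that list (adjusted p = 0.0030) was lost at an adjusted p = 0.43 with an estimated correlation. Of 32 pregranulosa and supporting cell genes 2 rose, Gng13 (4.17-fold) and the R-spondin receptor Lgr5 (3.36-fold), and 2 fell, Sprr2d and Nr0b1 (2.19-fold). In the retinoic acid list Aldh1a1, which makes retinoic acid from retinaldehyde, rose 3.61-fold from 535 to 1967.

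At an unadjusted limma p under 0.05, 3702 probe sets differed from 12.5 to 14.5 dpc and more, 3879, from 14.5 to 16.5 dpc. The interval from 11.5 to 12.5 dpc was shorter than the others. Past the adjusted threshold 412 probe sets changed from 12.5 to 14.5 dpc, 269 upward and 143 downward, the most of the 4 intervals by that threshold. The count was 112 without 12.5 dpc replicate 1 and 133 without 12.5 dpc replicate 2. It was 221 without 14.5 dpc replicate 1, 153 without 14.5 dpc replicate 2, and 815 and 830 without replicate 1 and replicate 2 of 11.5 dpc.

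**Figure D2:**
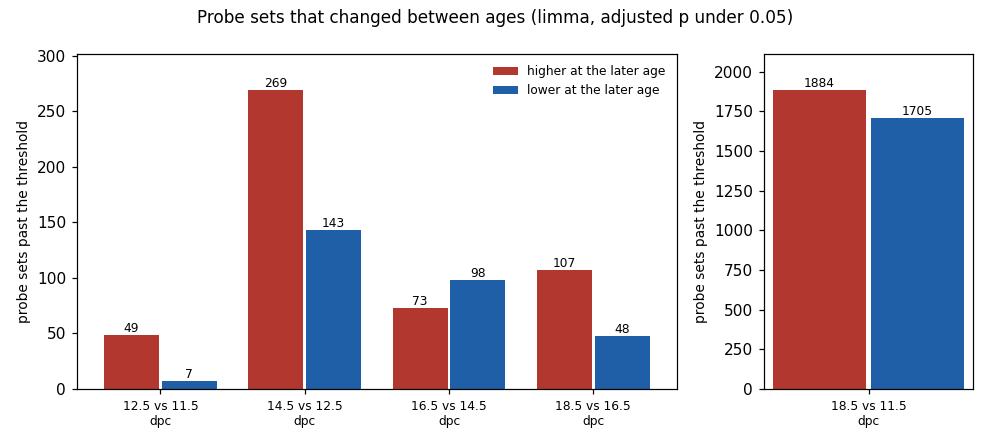
Number of probe sets past an adjusted p of 0.05 in limma, higher or lower at the later age, for the 4 intervals and, on an axis of its own, for 18.5 against 11.5 dpc. The bars run from 7 lower at 12.5 dpc to 1884 higher at 18.5 than at 11.5 dpc.

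From 14.5 to 16.5 dpc embryonic globins and some of the pluripotency genes fell. The embryonic globin Hbb-y fell 15.8-fold, from 7500 ± 300 to 461 ± 36.7 (SD, n = 2; limma adjusted p = 2.8e-08). Dppa3, a germ cell and oocyte protein, fell 9.40-fold, from 413 ± 93.6 to 29.2 ± 5.6, Sox2 fell 7.49-fold and Stra8 6.87-fold, to 72.8 ± 14.6. The X-linked homeobox genes Rhox9 and Rhox5 fell 10.2-fold and 6.71-fold. Of 23 genes of primordial germ cells and pluripotency 6 fell and none rose, and 8 fell when adjusted over the list alone (median log2 change -0.79, camera adjusted p = 5.0e-23, and adjusted p = 1.9e-07 with an estimated correlation). Dppa5a fell 6.41-fold and Dppa4 4.68-fold, and Pou5f1 fell from 112 ± 13.6 to 26.2 ± 6.4 (adjusted p = 0.011). Of 18 erythroid genes the embryonic globins Hbb-y, Hba-x (6.32-fold) and Hbb-bh1 (3.50-fold) fell and 15 did not pass, and 3 fell and 2 rose when adjusted over the list alone (list adjusted p = 1.5e-08, and adjusted p = 0.0010 with an estimated correlation). Of 29 genes of meiotic prophase Stra8 and Trip13 (2.87-fold) fell and 27 did not pass, and 4 fell and 2 rose when adjusted over the list alone. Sycp1 was not called at 322 ± 117 and 679 ± 97.3 (adjusted p = 0.053).

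The largest rises in this interval were in Trmt13, a tRNA methyltransferase (5.37-fold), and Fbxo43, an inhibitor of the anaphase-promoting complex (5.18-fold), followed by Lcmt1 (3.93-fold), Kcp (3.93-fold), Cspp1 (3.72-fold) and Igfbp6 (3.25-fold). Of 39 mesenchyme and matrix genes Col1a1 (2.95-fold), elastin, Eln (2.88-fold), and Mfap4 (2.16-fold) rose and 10 rose when adjusted over the list alone. The list was higher at an adjusted p = 1.5e-06, but at an adjusted p = 0.13 with an estimated correlation. Id1, a target of BMP signalling, rose 1.92-fold and was 1 of 39 genes of the TGF-beta, activin and BMP list to pass (list adjusted p = 0.027, and adjusted p = 0.042 with an estimated correlation). With fry the list did not pass (adjusted p = 0.074). Without 14.5 dpc replicate 1 or 16.5 dpc replicate 1 this list was not called (adjusted p = 0.051 and 0.064). None of 51 cell cycle and DNA replication genes passed over all probe sets, while 18 fell and 2 rose when adjusted over the list alone (median log2 change -0.37, adjusted p = 5.5e-09, and adjusted p = 0.0038 with an estimated correlation). Of 16 genes of testis Sertoli and Leydig cells Rhox5 and Dmrt1 (3.47-fold) fell and none rose, with 4 falling and 2 rising when adjusted over the list alone (list adjusted p = 0.0030, but adjusted p = 0.085 with an estimated correlation, and 0.076 without 16.5 dpc replicate 2). Foxl2 had 351 ± 33.0 and 825 ± 46.6 and was not called (adjusted p = 0.086).

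In all, 171 probe sets changed from 14.5 to 16.5 dpc, 73 upward and 98 downward, but without 14.5 dpc replicate 1 the split was 42 upward and 35 downward. The count was 30 without 16.5 dpc replicate 2, 75 without 16.5 dpc replicate 1, 77 and 46 without replicate 1 and replicate 2 of 14.5 dpc, 75 without either sample of 12.5 dpc, 79 and 83 without replicate 1 and replicate 2 of 18.5 dpc, and 562 and 564 without replicate 1 and replicate 2 of 11.5 dpc.

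From 16.5 to 18.5 dpc the largest rises included genes of oocytes. Dppa3 rose 26.1-fold, from 29.2 ± 5.6 to 1162 ± 108 (SD, n = 2; limma adjusted p = 1.4e-06). Ccno, cyclin O, rose 21.4-fold, the transcription factors Lhx8 and Nobox 12.6-fold and 12.2-fold, Nlrp4f from 1.6 to 178 and the splicing factor Esrp1 9.98-fold. Of 27 tested genes of oocytes and folliculogenesis 9 rose, none fell and 18 did not pass, and 16 rose when adjusted over the list alone (median log2 change 0.70, camera adjusted p = 2.5e-40, and adjusted p = 2.6e-30 with an estimated correlation). Figla, another oocyte transcription factor, was not called in this interval, at 109 ± 25.9 and 275 ± 42.1 (adjusted p = 0.13). Of 23 genes of primordial germ cells and pluripotency 5 rose and none fell, and 7 rose and 1 fell when adjusted over the list alone. The 5 were Dppa3, Trim71 (8.98-fold), the receptor Kit (6.33-fold, 34.8 ± 3.9 to 305 ± 21.8), Tcl1 (3.68-fold) and Dppa4 (3.15-fold, named after its value was seen), of which Dppa3, Kit and Tcl1 are also in the oocyte list. Pou5f1 was not called, at 26.2 ± 6.4 and 36.5 ± 1.2. The list's median log2 change was 0.03 and its mean 0.69 (adjusted p = 4.1e-14, and adjusted p = 0.00011 with an estimated correlation). In the germ cell RNA and piRNA list Gtsf1 rose 3.93-fold to 2705 ± 334, and 6 of 16 rose when adjusted over the list alone (list adjusted p = 1.3e-05, and adjusted p = 0.0041 with an estimated correlation).

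The largest falls were in the histocompatibility gene H2-K2 (8.96-fold), Rab27b (5.43-fold), Ugt8a (5.12-fold), the cytokine Il33 (4.48-fold), Ctbs (3.57-fold) and the meiotic cohesin Stag3 (3.26-fold, from 3966 ± 579 to 1206 ± 195). Of 29 genes of meiotic prophase Stag3 and Stra8 (2.78-fold) fell and 27 did not pass, and 4 fell and 1 rose when adjusted over the list alone (list adjusted p = 0.0099, but adjusted p = 0.13 with an estimated correlation, and 0.081 and 0.10 without replicate 1 of 16.5 and of 18.5 dpc). Of 39 mesenchyme genes Mfap4 (2.30-fold), Maf (2.13-fold) and Fbn2 (2.07-fold) fell, and 11 fell when adjusted over the list alone (list adjusted p = 1.3e-05, but adjusted p = 0.17 with an estimated correlation, and 0.061 without 16.5 dpc replicate 1). None of the 32 pregranulosa genes passed over all probe sets or over the list alone, and the list's call (adjusted p = 0.0094) was lost at an adjusted p = 0.47 with an estimated correlation and at 0.11 without 16.5 dpc replicate 2. None of 20 endothelial genes passed (list lower, adjusted p = 0.015, and adjusted p = 0.045 with an estimated correlation, but 0.063 without 16.5 dpc replicate 1). None of 23 imprinted genes passed, with 6 lower and 1 higher when adjusted over the list alone (list lower, adjusted p = 0.0023, and adjusted p = 0.048 with an estimated correlation). With fry the imprinted list did not pass (adjusted p = 0.054). The erythroid list was higher with no gene passing, and 4 rose and 1 fell when adjusted over the list alone (adjusted p = 0.017, but adjusted p = 0.21 with an estimated correlation, and 0.12 and 0.073 without 16.5 dpc replicate 2 and 18.5 dpc replicate 1). Id1 rose a further 2.71-fold to 2012, and in the Notch list the ligand Jag2 rose 7.70-fold and the target Hes1 2.00-fold, though that list as a whole was not called (adjusted p = 0.13).

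In all, 155 probe sets changed from 16.5 to 18.5 dpc, 107 upward and 48 downward. The count was 33 and 38 without replicate 2 and replicate 1 of 18.5 dpc, 37 and 69 without replicate 1 and replicate 2 of 16.5 dpc, 93 and 92 without replicate 1 and replicate 2 of 12.5 dpc, and 240 and 242 without replicate 1 and replicate 2 of 11.5 dpc.

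Over the whole course, from 11.5 to 18.5 dpc, the lists of meiosis, oocytes and germ cell RNA were higher at the later age and that of the cell cycle was lower. The germ cell lists share some members. Dazl is in those of meiosis and germ cell RNA, and Ddx4 in those of germ cell RNA and oocytes. Sycp1 rose 50.6-fold, from 2.2 ± 1.3 to 903 ± 30.4 (SD, n = 2; limma adjusted p = 4.5e-08). Gtsf1, which acts in the piRNA pathway, rose 35.4-fold, Lhx8 28.3-fold, Gng13, a G protein subunit, 27.3-fold, Terb1 17.5-fold, Ccno 15.8-fold and the synaptonemal complex gene Syce1 12.9-fold. The adult globin Hbb-b2 rose 14.6-fold, to 7894 ± 171, and the plasma protein genes Alb and Apoa1 rose 15.6-fold and 14.0-fold, to 715 ± 12.1 and 329 ± 2.5. The embryonic globin Hba-x fell 63.2-fold, from 4603 ± 418 to 57.1 ± 7.4, and Hbb-y 12.3-fold. Cpa1 fell 28.2-fold, Hmga2, a chromatin protein of embryonic tissues, 14.5-fold, Sox2 13.8-fold, Rhox9 10.8-fold, the digestive enzyme Mgam 10.5-fold, the ubiquitin ligase subunit Skp2 9.90-fold, Cpne8 9.43-fold and the condensin subunit Ncapd2 8.80-fold.

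Of 16 genes of germ cell RNA and piRNA machinery 12 rose and 13 did when adjusted over the list alone, the others not passing. Besides Gtsf1 they included Dazl (11.3-fold), Piwil2 (8.15-fold) and Mov10l1 (5.76-fold), and Ddx4 rose from 63.6 ± 31.0 to 341 by its probe set on array A (list median log2 change 1.52, camera adjusted p = 9.5e-17, and adjusted p = 5.5e-09 with an estimated correlation). The other Ddx4 probe set had 196 ± 64.8 and 135 ± 12.1 and was not called. The other Dazl probe set changed less, from 42.1 and 43.6 in the samples of 11.5 dpc to 71.1 and 42.9 in those of 18.5 dpc. Of 27 oocyte and folliculogenesis genes 15 rose and none fell, and 17 rose when adjusted over the list alone (adjusted p = 3.1e-14, and adjusted p = 1.5e-10 with an estimated correlation). Nobox rose 12.7-fold, Ybx2 10.3-fold and Nlrp5 9.29-fold, and Figla rose from 21.3 ± 19.2 to 275 ± 42.1. Gdf9 rose less, from 87.4 ± 4.1 to 153 ± 16.2 (adjusted p = 0.044), and was not called without either sample of 11.5 or of 18.5 dpc. Zp2 rose from 36.8 ± 7.0 to 100.4 ± 7.6, and no probe set of Zp1, Zp3 or Amh reached the filter. Of 29 genes of meiotic prophase 13 rose and 1 fell, and 17 rose and 1 fell when adjusted over the list alone (adjusted p = 7.4e-13, and adjusted p = 7.9e-07 with an estimated correlation). Stra8, at 2.7 ± 0.7 and 16.4 ± 9.4, was not called between these ages. Of 23 genes of primordial germ cells and pluripotency 8 fell and 4 rose, and 9 fell and 4 rose when adjusted over the list alone (adjusted p = 0.00020, but adjusted p = 0.096 with an estimated correlation). Besides Sox2 the falls included Dppa5a (6.02-fold), Tfap2c (5.87-fold) and Utf1 (4.82-fold), whereas Dppa3 and Kit rose.

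Of 51 cell cycle and DNA replication genes 27 fell, 1 rose and 23 did not pass, and 29 fell and 2 rose when adjusted over the list alone (median log2 change -0.64, camera adjusted p = 6.0e-13, and adjusted p = 0.00018 with an estimated correlation). The kinase Aurkb fell 4.82-fold, Rrm1 3.43-fold, Top2a 3.39-fold and Cdc25c 3.35-fold. Of 32 pregranulosa and supporting cell genes 9 rose, 7 fell and 16 did not pass, and 11 rose and 11 fell when adjusted over the list alone. The list's median log2 change was -0.14 and its mean 0.20, and it was not called (adjusted p = 0.35). Foxl2 rose 6.89-fold, Irx3 8.64-fold and Lgr5 7.63-fold, and Fst 4.16-fold, while Wnt4 (1613 ± 312 and 1202 ± 80.3), Nr5a1 (945 ± 399 and 557 ± 0.8) and Sox9 (858 ± 48.9 and 590 ± 120) were not called. The other Fst probe set changed less, from 78.9 and 131.7 in the samples of 11.5 dpc to 123.8 and 177.7 in those of 18.5 dpc. The Wnt4 probe set used had an added r in its suffix. The plain Wnt4 probe set, on array A, had 113.9 and 209.3 at 11.5 dpc and 117.9 and 118.3 at 18.5 dpc. The Sox9 probe set used here had an added f in its suffix and may not be specific to the gene. The other tested Sox9 probe sets disagreed. One fell, from 81.5 ± 12.2 to 19.4 ± 18.2 (adjusted p = 0.046), and the other was not called at 102 ± 62.6 and 169 ± 1.8. The untested Sox9 probe sets, on array C, had signals of at most 36.9 and 35.4 in any sample. These values do not show how high Sox9 was in the ovary. Kitl, the ligand of Kit, rose from 862 ± 117 to 1466 ± 120, whereas Bmp2 was not called at 362 ± 178 and 394 ± 3.3. Between these ages Bmp2 was higher, with 1395.9 and 796.0 in the samples of 14.5 dpc. The other tested Bmp2 probe set had 14.7 and 12.7 at 11.5 dpc and 55.5 and 32.1 at 18.5 dpc.

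Of 39 mesenchyme and matrix genes 12 rose and 3 fell, and 14 rose and 5 fell when adjusted over the list alone. They included Eln (11.2-fold), Mgp (9.15-fold), Lox (3.43-fold) and Col1a1 (3.42-fold), and the list had an adjusted p = 0.0011, but an adjusted p = 0.32 with an estimated correlation. Of 15 genes of surface epithelium 6 rose and 3 fell, and 8 rose and 3 fell when adjusted over the list alone, with Krt19 at 10.7-fold, Lgals7 at 3.64-fold and Krt8 at 3.58-fold (list adjusted p = 0.0014, but adjusted p = 0.15 with an estimated correlation). Of 20 endothelial genes 7 fell and none rose, and 8 fell and 2 rose when adjusted over the list alone, with Emcn 3.78-fold, Cdh5 3.45-fold, Tie1 2.96-fold and Cd34 2.58-fold lower (list adjusted p = 0.035, but adjusted p = 0.085 with an estimated correlation, and 0.16 without 11.5 dpc replicate 2). Of 23 imprinted genes 9 fell and 3 rose, both over all probe sets and when adjusted over the list alone. Plagl1 fell 4.30-fold, Peg12 4.19-fold, Peg10 3.70-fold and Nnat 2.69-fold (list adjusted p = 0.015, but adjusted p = 0.13 with an estimated correlation, and 0.10 without 11.5 dpc replicate 2). Of 18 erythroid genes 3 rose and 3 fell, and 4 rose and 3 fell when adjusted over the list alone, and the list was not called (adjusted p = 0.19).

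In all, 3589 probe sets (14.5%) differed between 18.5 and 11.5 dpc, 1884 higher and 1705 lower, and 2194 of them by at least 2-fold. By genes, 2205 of 12589 changed, 1151 up and 1054 down. Of 1503 other tested probe sets of the called genes 71.7% had the same sign, and 27 probe sets of 25 genes were called in the opposite direction. Of 217 named changes over the 5 comparisons, 11 had another tested probe set with the opposite sign, none of which was called; these were changes of Pou5f1, Utf1, Mov10l1, Rrm1, Cspp1, Eln, Trp63, Ddx4 and Xist. The count was 1562 without 18.5 dpc replicate 1, 1743 without 18.5 dpc replicate 2 and 2348 when only the arrays of the 2 ages were fitted. Which direction held more calls depended on the scaling and the samples: it was 1605 higher and 1861 lower with median scaling, 1797 and 1827 with quantile normalization, 778 and 784 without 18.5 dpc replicate 1, and 841 and 902 without 18.5 dpc replicate 2.

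**Figure D3:**
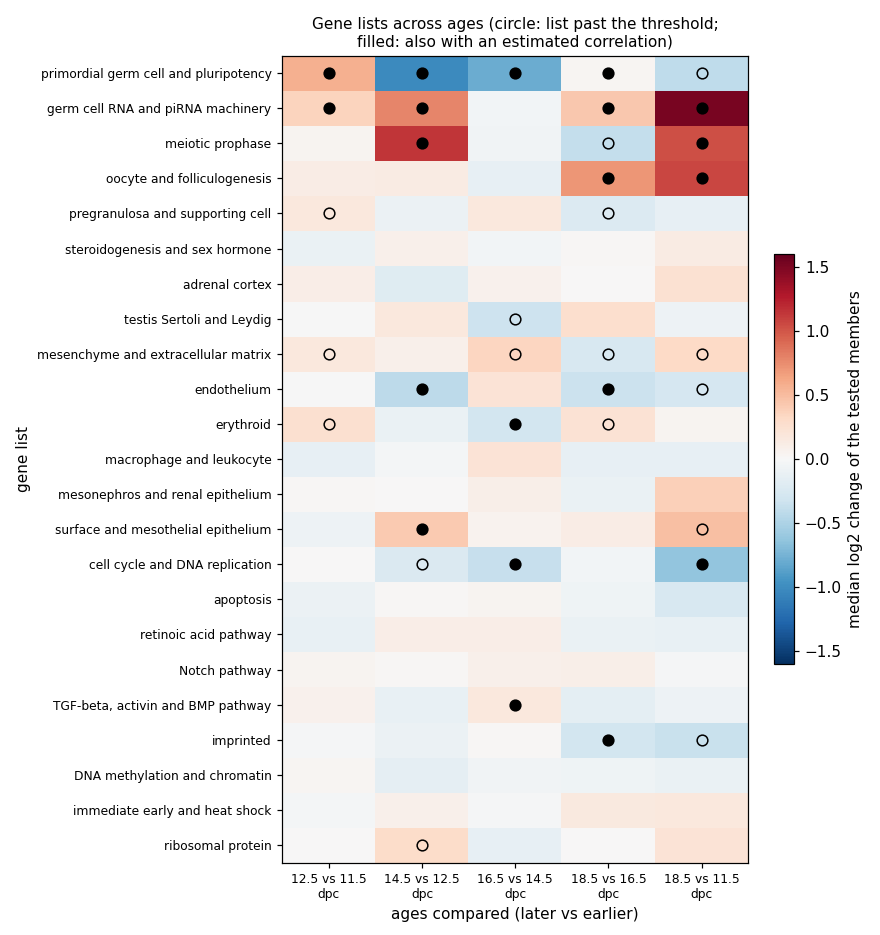
Median log2 change of the tested members of 23 gene lists (rows) in the 5 comparisons (columns), colour from lower (blue) to higher (red) at the later age. A circle marks each of the 36 list tests past the threshold, filled for the 20 that also passed with an estimated correlation.

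Over the 115 list tests 36 passed the threshold, 20 upward and 16 downward, and 20 of the 36 also passed with an estimated correlation. The lists of steroidogenesis, adrenal cortex, macrophages, mesonephros, apoptosis, retinoic acid, Notch, DNA methylation and chromatin, and immediate early and heat shock genes did not pass in any comparison. Some of their members did between 11.5 and 18.5 dpc. Of 15 steroidogenic genes 5 rose and 2 fell: Cyp11a1, the first enzyme of steroid synthesis, fell 2.74-fold to 18.7 and Inha, inhibin alpha, 2.42-fold, while the oestrogen receptor Esr1 rose 3.07-fold. Of 22 Notch genes 2 rose and 1 fell, of 29 apoptosis genes 1 rose and 4 fell, and of 33 chromatin genes 2 rose and 3 fell. In the retinoic acid list 4 of 14 genes rose, Aldh1a1 4.66-fold and Rbp4 4.35-fold among them, and 5 fell, Crabp2 4.12-fold and Crabp1 2.21-fold among them. In the chromatin list the methyltransferase Ezh2 fell 2.44-fold and Cbx2 2.38-fold, and in the apoptosis list Bbc3 fell 5.17-fold and Cycs 3.38-fold.

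Genes that mark sex were read in each sample. The 5 Y-linked genes of the list on the arrays had 9 probe sets, none of which passed the filter, and their highest signal on any array was 47.3. Xist, which is expressed from the inactive X chromosome, had signals of 74.7 and 236 in replicates 1 and 2 of 11.5 dpc and mean signals of 375 ± 31.7, 222 ± 103, 358 ± 28.3 and 347 ± 16.2 at the later ages. Its rise from 11.5 to 18.5 dpc (log2 change 1.26, adjusted p = 0.043) passed the threshold, but without 11.5 dpc replicate 1 it was 0.52 and did not (adjusted p = 0.29).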

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

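Of 36 list calls 17 were kept in all 23 settings and 19 were lost in at least 1, 12 of them without at least 1 of the samples, and no list call turned its direction. No scaling moved the median change of all genes by over 0.1 on the log2 scale. Of 217 named values past the threshold, between 153 (without 18.5 dpc replicate 1) and 216 (pseudocount 32) stayed past it. The only value that changed sign was Rps28 from 11.5 to 18.5 dpc, 0.66 on the log2 scale in the planned analysis and -0.035 with quantile normalization (adjusted p = 0.87).

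The 12.5 against 11.5 dpc count of 56 was 6 with no filter, 32 with quantile normalization, 30 with median scaling, 4 with no intensity trend and 2 with only the 2 ages compared. The 14.5 against 12.5 dpc count of 412 was 271 with no intensity trend. The 16.5 against 14.5 dpc count of 171 was 101 with no filter, 76 with no intensity trend and 96 with only the 2 ages compared. The 18.5 against 16.5 dpc count of 155 was 88 with a pseudocount of 1. The 18.5 against 11.5 dpc count of 3589 was 2348 with only the 2 ages compared and 2194 with a change of at least 2-fold as well. The share highest at 18.5 dpc, 29.1%, was 30.9% with no filter and 32.1% with no intensity trend. The 36 list calls were 20 with an estimated correlation, 38 with the mean t of all probe sets, 31 on array A only and 36 with plain suffixes, an alternative chosen after seeing the data.

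With the replicate number as a block, the 12.5 against 11.5 dpc count was 32, and the other counts were 329, 150, 126 and 3415. Deviations of the same number at different ages had an r from -0.161 to 0.219 with a median of -0.013. The highest was that of 11.5 and 14.5 dpc, 0.219, 0.098 and 0.070 on arrays A, B and C, and the labels do not say that the numbers pair the samples.

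With 1 sample left out in turn, the remaining sample of that age had no spread of its own and took that of the other ages. The F test count ran from 1812 without 18.5 dpc replicate 1 to 4366 without 11.5 dpc replicate 2. The interval counts ran from 2 (without 12.5 dpc replicate 2) to 553, from 112 (without 12.5 dpc replicate 1) to 830, from 30 (without 16.5 dpc replicate 2) to 564 and from 33 (without 18.5 dpc replicate 2) to 242, each highest without 11.5 dpc replicate 2. The 18.5 against 11.5 dpc count ran from 1562 without 18.5 dpc replicate 1 to 3478 without 14.5 dpc replicate 2, and the share highest at 18.5 dpc from 25.4% without 18.5 dpc replicate 1 to 31.4% without 16.5 dpc replicate 2.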

Other observations

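Globin genes changed at different ages. The embryonic genes did not fall together: Hba-x fell 5.60-fold from 12.5 to 14.5 dpc and 6.32-fold in the next interval, while Hbb-y had a mean signal of 7500 at 14.5 dpc and fell 15.8-fold after it. The adult gene Hbb-b2 rose 2.60-fold from 11.5 to 12.5 dpc and 4.08-fold from 12.5 to 14.5 dpc.

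Some genes did not change in 1 direction only. Ap2b1 had a mean signal of 556 ± 75.0 (SD, n = 2) at 12.5 dpc, against 76.0 ± 5.5 at 11.5 dpc and 75.8 ± 41.1 at 14.5 dpc, and was at 242 ± 65.0 at 16.5 dpc. Dppa3 dipped to 29.2 ± 5.6 at 16.5 dpc between 413 ± 93.6 and 1162 ± 108, and both the fall and the rise were called. Kit was also lowest at 16.5 dpc, at 34.8 ± 3.9 between 83.1 ± 18.2 and 305 ± 21.8, but only its rise was called.

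The patterns below were picked after the results were seen, so all of their tests were chosen after that. The explanations were tested with marker lists and conditions written before the marker signals were seen, except the test of 5 abundant liver genes, which was chosen after they had been seen.

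Alb and Apoa1, both abundant in liver, were among the 10 largest rises from 11.5 to 18.5 dpc. Alb was already at 171 ± 33.7 at 14.5 dpc and 146 ± 27.4 at 16.5 dpc, against 31.9 ± 13.9 at 11.5 dpc. Apoa1 had 25.1 and 131.4 in replicates 1 and 2 of 14.5 dpc. The tests below concern the 18.5 dpc samples only, so liver RNA in earlier samples was not tested. If liver tissue or liver RNA had entered the 18.5 dpc samples, at least 50% of the other tested liver secretory genes were to rise, and 5 of 9 did (55.6%): Ahsg, Fga, Fgg, Itih2 and Rbp4, the last also in the retinoic acid list. This decides nothing, because all 5 passed the signal filter only through the 18.5 dpc samples in which they were high. The 5 are 23.8% of all 21 other liver genes on the arrays. That share decides nothing either, because only 9 of the 21 were tested and it counts each untested gene as one that did not rise. The test chosen afterwards does not settle it either: 0 of 5 genes abundant in fetal liver reached a mean signal of 100 at 18.5 dpc, with Afp at 44.1, Ttr at 48.9, Apoa2 at 30.6, Apob at 27.2 and Serpina1a at 26.2, but none of these probe sets is known to work on these arrays. Liver RNA stays open, as does a change with age in ovarian cells, which was not tested.

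Cpa1 and Mgam, digestive enzymes, were among the 10 largest falls. Pancreatic or gut tissue in the early samples would bring other such genes, and 3 of 19 on the arrays (15.8%) had a mean signal of at least 100 at 11.5 dpc that was above the one at 18.5 dpc, which is below the bound set beforehand. That bound could not exclude it, because only these 3 reached 100 on any array and 11 of the 19 stayed below 50 on every array. Of the 3, Pnliprp2 had 126 ± 50.8 and 25.0 ± 11.9, while Cel (158 and 157) and Ctrb1 (276 and 271) were nearly level. Such tissue stays open, as does a change with age in the ovary itself, which was not tested.

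Xist was lower in 11.5 dpc replicate 1 than in replicate 2, by 1.48 on the log2 scale, and 0.534% of tested probe sets of array A differed more between these samples. The median difference of all tested probe sets of array A was 0.07, which is 4.91% of that of Xist. This does not decide on a general loss of signal, because scaling every array to the same mean can remove such a loss. Scaling did not make the medians equal. Array A of replicate 1 had the lowest median signal of its type, 47.0 against 54.2 in replicate 2. Of its tested probe sets 56.7% were higher in replicate 2. Male tissue in that pool could lower Xist, and 0 of 9 Y-linked probe sets had their highest signal in that sample, but no Y-linked signal reached 50 on any array. So male tissue in the pool of 11.5 dpc replicate 1 could not be excluded by this test. Xist was not alone in differing between the samples of 11.5 dpc. In replicates 1 and 2 Fst had 22.7 and 71.0 and Dazl 35.0 and 91.5, while Pou5f1 had 250 and 193 and Dppa3 480 and 322. Xist also differed at 14.5 dpc, with 295 and 149 in replicates 1 and 2. No biological explanation was tested for these differences.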
